A study of Homo sapiens with 19 samples.

How the data were processed

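Gene expression was measured in 19 human tissue samples, 10 endometriomas and 9 control endometrium samples, with Illumina Human WG-6 version 2 BeadChips, which carry oligonucleotide probes on beads and read 1 sample per array. Per the labels, every sample came from a different patient and the groups were not paired. A group therefore has independent biological replicates, and no sample was measured more than once.

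Per the file headers, each sample's deposited table gave for every one of 48701 probes an intensity (the average bead signal, on a linear scale), a detection score and the number of beads. The authors used BeadStudio, per the submitters' processing notes, and its version was not given in the sources used here. The deposited detection score lies between 0 and 1 and is high where a probe lies above the negative controls, so the detection p was taken as 1 minus the score. A second deposited table held the authors' processed intensity values for the same arrays. Every one of its columns had the same distribution, with a median of 76.7, quartiles of 58.9 and 182.2 and a maximum of 45053.3, so its columns had been brought to the same distribution on a linear scale. Which method the authors used for that, and whether a background was subtracted before it, stayed unknown. In 18 samples the column was a rising function of that sample's own intensities. In 1 sample it was not, with a Spearman correlation of 0.970 over detected probes with its own file and at most 0.939 with any other file. The values used in the main results came from the sample files, so that column entered only the alternative based on the authors' table.

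The sample files and the processed table numbered probes in different ways. They were joined through the exact order of values in the 18 arrays, which matched all 48701 probes to a single row each. Of these probes, 23687 had 1 gene symbol in the platform annotation, 35 had several and 24979 had none here. Only probes with exactly 1 symbol were named. The symbols covered 18774 genes, none needed an update through its gene identifier, and 36 named probes had an identifier outside the gene table. No genome was used here, so no coordinates are given.

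Intensities were background-corrected with limma's neqc (normexp, with the negative-control level inferred from the detection p), an offset of 16 was added, and values were quantile normalized and moved to the log2 scale. Values are therefore normalized log2 intensities, and differences of dim genes are understated by the offset. A probe was tested when its detection p lay under 0.01 in at least 9 samples, which left 18642 probes, 14364 of them named. The probe with the highest mean over all samples stood for its gene, giving 12530 genes. Among the 1482 genes with more than 1 such probe, only RTN4 had probes called in opposite directions. The 79 probes of XIST, TSIX and Y-linked genes were left out of every table.

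Endometriomas and controls were compared with limma (lmFit and eBayes, version 3.58.1 in R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over the 12530 genes and a threshold of 0.05. The moderated test had 19.82 degrees of freedom. Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 36 lists, and again with the correlation estimated for each list. limma's fry, which tests whether a list's genes move on balance in 1 direction, was run beside camera. In subsets of samples camera was run at the preset correlation only. The within-group spread was compared with an exact permutation test. Figures were drawn with matplotlib 3.10.9. A gene whose probe was not detected in any sample of a group had only a bound there. Its fold was computed against the higher of the probe's own value and the lowest detected signal on each array, and is given as "at least".

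The main tests, the 36 gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except the alternatives and tests named in the text as chosen after seeing the data. The rule took the 12 largest rises and 12 largest falls past the threshold for which every sample of the higher group lay above the other group's median, then from each list up to 4 members with the smallest adjusted p and up to 2 that passed in the opposite direction, and finally a preset group of genes that included the steroid receptors. Of the preset genes, HOXA10 and HOXA11 were not analysed here. CYP19A1, STAR and GATA4 fell below the detection filter and are given from the fit without it. Scores of a list are the mean log2 intensity of its tested members in a sample.

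The steps were tested on simulated data for 10 against 9 samples, built from the means and residual spread of the 12530 genes. Of 67 genes changed by 0.5 on the log2 scale, 10.4% were recovered. Recovery was 68.7% of 67 genes at 1 and 92.4% of 66 genes at 2. Of 120 calls, 6 were unchanged genes, no interaction call was made where none was simulated, and camera called 0 of 36 unshifted lists. The simulated genes were independent of each other, which real genes are not. Only 200 of the 12530 were changed, whereas 17.21% were called in the data. The Benjamini-Hochberg threshold depends on that share, so recovery in the data can differ from these values.

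Between 33.66% and 42.13% of probes were detected per sample, the median probe was read by 38 to 41 beads, and the median raw intensity lay between 49.1 and 69.7. The raw intensity above which the brightest 1% of probes lay differed more, from 2433.1 to 7648.9, before quantile normalization. The number of arrays limits the precision of every value. The menstrual cycle phase and the position of arrays on BeadChips were not given in the sources used here. Descriptions of the samples followed different naming styles, a code beginning with CW or EM (5 endometriomas and 7 controls) or another form (5 endometriomas and 2 controls), and this style was used as a stand-in for a possible collection round. Per the titles, most endometriomas of the other form had a patient code beginning with M, which no control had. What that code marks was not given. A round marked by it could not be told apart from the group within that style.

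Alternatives covered the background correction, the centring, the authors' processed table, the detection filter, the choice of probe, the description style, array weights, the variance model, an exact rank-sum test, a stricter threshold, and leaving out each sample in turn. A block for the BeadChip could not be fitted because no file used here names the chips.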

Results

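Endometriomas are ovarian cysts lined by endometrium-like tissue, and the study compared them with endometrium of control patients. Whole tissue was profiled, so every value is an average over epithelium, stroma, blood vessels and immune cells. The 10 endometriomas and 9 control samples each came from a different patient. Levels are normalized log2 intensities and differences are endometrioma minus control, with the standard error of the limma fit. Adjusted p-values of genes are from limma and those of gene lists from limma's camera. Between 33.66% and 42.13% of probes were detected per array.

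In endometriomas all 25 tested epithelial genes and 10 of 13 reproductive tract transcription factors were lower. Higher were 20 of 24 macrophage, 16 of 33 fibrillar and fibrosis matrix and 9 of 21 complement genes. With an estimated correlation these 5 lists had adjusted p-values from 0.290 to 0.323. Among called genes with every sample of the higher group above the other group's median, the largest rise was that of COL8A1. This collagen gene was 38.4-fold higher (log2 difference 5.26 ± 0.63, adjusted p = 6.12e-05). CLDN11 was 30.5-fold and COL10A1 29.2-fold higher, each detected in only 1 of 9 controls, and COL11A1 24.3-fold higher, detected in 5 of 9. By the same rule the largest falls were those of SCGB2A1 and FOXA2. The secretoglobin SCGB2A1 was 50.6-fold lower (log2 difference −5.66 ± 1.20, adjusted p = 0.00360). The gland regulator FOXA2 was 34.6-fold lower (−5.11 ± 0.75, adjusted p = 0.000237) and detected in only 1 of 10 endometriomas. Of 12530 genes tested, 1050 were higher and 1107 lower in endometriomas at an adjusted p under 0.05, and 608 and 520 of these differed at least 2-fold. The groups did not overlap in any sample for 56 genes, 0.447% of those tested, where chance gives 0.00217%. Among these were the steroid-activating enzyme HSD11B1, the glypican GPC3, the tight-junction gene CLDN11 and COL10A1.

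Other genes among the 12 largest rises that met the rule for named genes were PDLIM3, a muscle LIM-domain gene (4.29 ± 0.71), PTGIS, the prostacyclin synthase (4.27 ± 0.61), the imprinted gene DIRAS3 (4.07 ± 0.50) and HOXC6 (3.70 ± 0.63). DLK1, an imprinted gene of fetal and gonadal tissue, was detected in 9 of 10 endometriomas and in 0 of 9 controls and was at least 16.9-fold higher (adjusted p = 0.00137). Large falls were also seen for GABRP (−4.90 ± 0.84), C9orf152 (−4.72 ± 0.77), the conjugating enzyme UGT2B7 (−4.52 ± 0.83), the antimicrobial peptide DEFB1 (−4.44 ± 0.93) and GDF7 (−4.02 ± 0.76). MMP26, a metalloproteinase of endometrial epithelium, differed by −4.09 ± 1.28 (adjusted p = 0.0331). Its call was lost in 8 of the 19 fits that left out 1 sample, with differences from −4.69 to −3.52 across all 19.

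Many of the genes named with large differences were near background in the lower group, and their folds there depend on background levels. PLA2G5, FZD7 and CD22 were detected in 1 of 9 controls, HSD11B1, ESR2, MMP23B and NTRK2 in 2, and DIRAS3, AMHR2 and PLA2G2A in 3. C9orf152 was detected in 1 of 10 endometriomas, GABRP, PRSS8, HSD17B2 and FOXJ1 in 3, and SCGB1D2, MMP26 and GDF7 in 4.

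**Figure D1:**
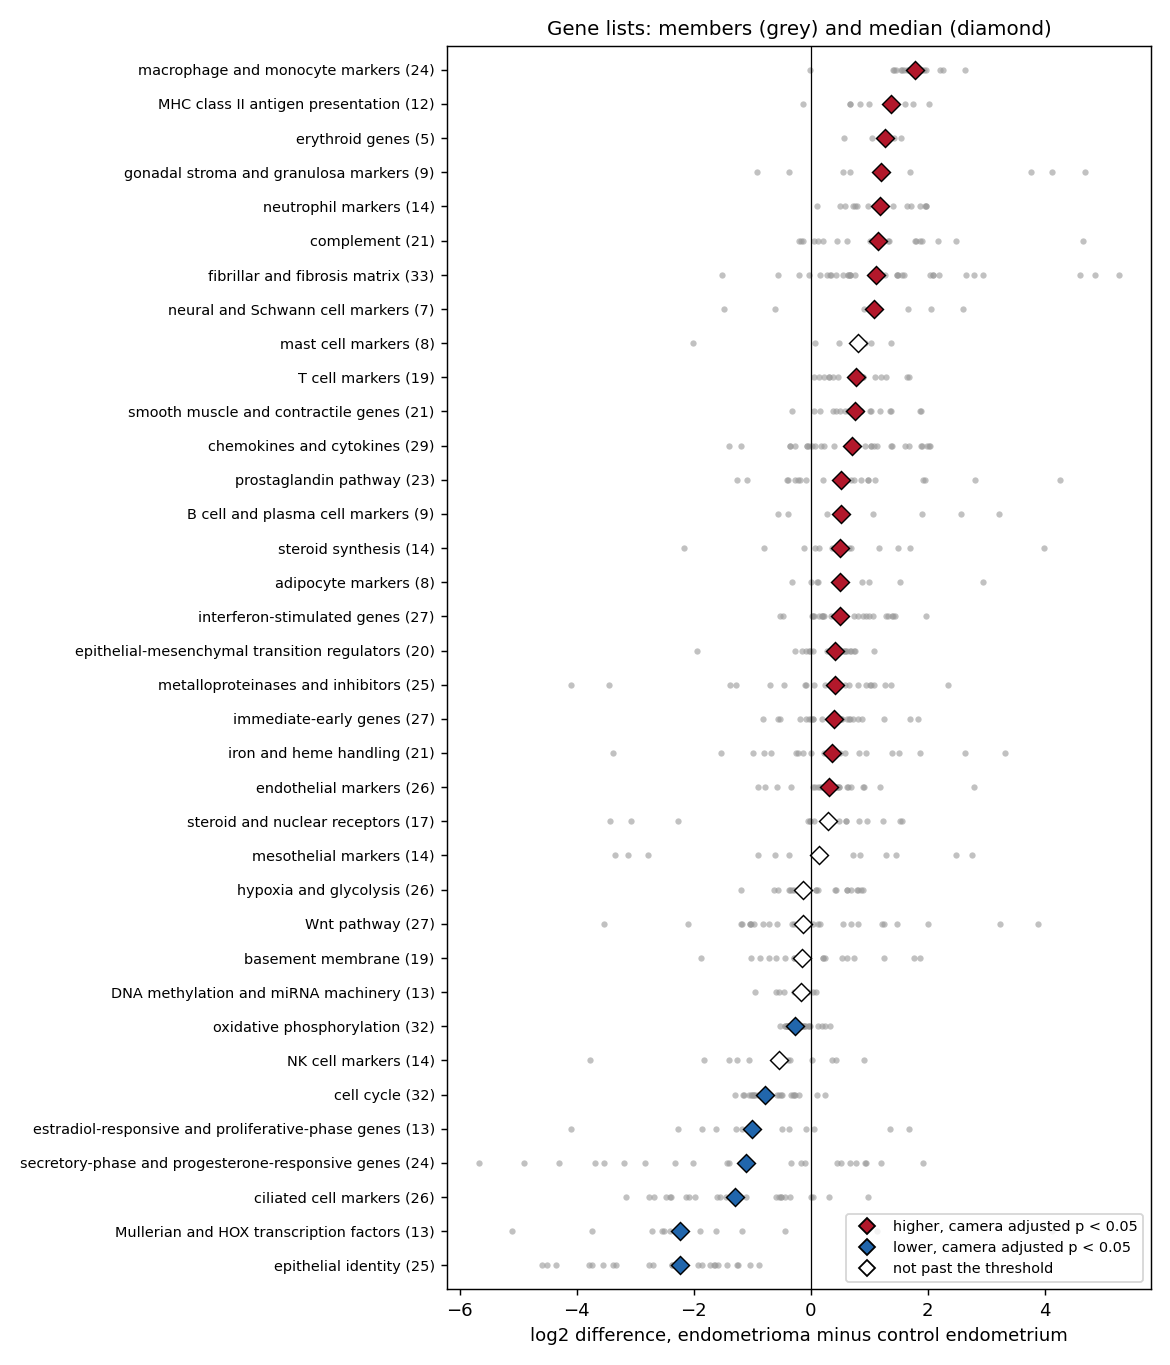
Each row is a gene list fixed before the data were examined, with its number of tested members in brackets; grey points are the log2 differences of members (endometrioma minus control endometrium) and the diamond is their median, filled where camera with the preset correlation called the list. The epithelial list has all 25 members below 0, while 20 of 24 macrophage members rose past the threshold; with an estimated correlation none of the 36 lists was called.

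Epithelial genes were lower as a group. All 25 tested members of the epithelial identity list fell, over all genes and when adjusted over the list alone, with a median log2 difference of −2.24. EPCAM, the epithelial adhesion molecule, averaged 6.66 ± 2.16 (SD, n = 10) in endometriomas and 11.16 ± 1.71 (SD, n = 9) in controls, a 22.6-fold difference (limma adjusted p = 0.00144). The membrane protease PRSS8 was 24.1-fold lower, the claudin CLDN3 20.4-fold lower and the epithelial factor EHF lower by a log2 difference of −3.39. CD24 fell with them (−4.45 ± 0.70, adjusted p = 0.000426). CDH1, which encodes E-cadherin, fell by 1.04 on the log2 scale (SE 0.32, adjusted p = 0.0286), a call lost in 3 of the 19 fits that left out 1 sample. Camera gave the list an adjusted p of 5.50e-16, and adjusted p = 0.323 with an estimated correlation. Ciliated cell genes followed the same direction, with 14 of 26 lower and none higher (adjusted over the list alone, 17 lower and 1 higher). FOXJ1, the regulator of motile cilia, differed by −3.16 ± 0.69 (adjusted p = 0.00452) and the ciliary gene CAPS by −2.76 ± 0.57 (adjusted p = 0.00320). The ciliated list had a median of −1.30 (camera adjusted p = 1.17e-05, and adjusted p = 0.373 with an estimated correlation).

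The falls were smaller in the other description style, whose separate analysis was chosen after seeing the data and which held only 2 controls. The difference between styles in the list scores did not pass for either list (limma interaction on scores, adjusted p = 0.163 for epithelial and 0.659 for ciliated genes). The median of the epithelial list was −2.70 in the samples with CW or EM codes and −0.60 in the other 7 samples, with camera adjusted p-values of 1.97e-21 and 0.0162. For ciliated genes the medians were −1.67 and −0.47, and the second was not past the threshold (adjusted p = 0.218). Both smaller values depended in part on 1 control that resembled the endometriomas. In the other style the difference of list scores was −0.79 for epithelial and −0.53 for ciliated genes, and −2.02 and −1.36 without that control, which leaves 1 control there. They also rest on 1 endometrioma of that style, with scores of 8.26 for epithelial and 8.41 for ciliated genes. The style's other endometriomas reached at most 6.32 and 5.84. Within the style no fit without that endometrioma was run.

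Transcription factors that pattern the female reproductive tract were also lower. Of 13 tested members of the Müllerian and HOX list, 10 fell and 2 rose, the same numbers as when adjusted over the list alone. EMX2 averaged 6.91 ± 0.68 (SD, n = 10) against 8.81 ± 0.62 (SD, n = 9), with no overlap between groups (limma adjusted p = 0.000324). MSX1 was 13.4-fold lower (−3.74 ± 0.52, adjusted p = 0.000168) and HOXD10 5.83-fold lower (−2.54 ± 0.35, adjusted p = 0.000168). TCF21, a mesodermal factor also found in gonadal stroma, went the other way and was 17.4-fold higher (4.12 ± 0.93, adjusted p = 0.00539). The list median was −2.23 (camera adjusted p = 8.99e-06, and adjusted p = 0.290 with an estimated correlation), with −1.79 and −1.34 in the CW or EM and other styles.

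Hormone-dependent endometrial genes fell in part. The cycle phase was not given, and scores of the secretory-phase list ranged from 7.40 to 10.85 among controls. Whole tissue cannot separate a changed hormone response from the lower epithelial transcripts. In the secretory-phase list 8 of 24 members fell and none rose (adjusted over the list alone, 11 fell and 1 rose), among them SCGB2A1, SCGB1D2 (29.7-fold, −4.89 ± 1.07) and the ectoenzyme ENPP3 (12.9-fold, −3.68 ± 0.79). HSD17B2, which inactivates estradiol, was 9.13-fold lower (−3.19 ± 0.74, adjusted p = 0.00635). The glycodelin gene PAEP differed by −2.83 ± 1.08 without passing (adjusted p = 0.0772). The list's median was −1.11 (camera adjusted p = 0.0219, and adjusted p = 0.373 with an estimated correlation). The call was lost without control replicate 3 (median −0.71, adjusted p = 0.104) and without control replicate 9 (median −0.88, adjusted p = 0.0545), and in the other description style the median was −0.14 (adjusted p = 0.982). The stricter detection filter moved it to −0.16 (adjusted p = 0.244) and array weights to −0.57 (adjusted p = 0.0950). In the estradiol-responsive list 5 of 13 members fell and 1 rose (adjusted over the list alone, 6 and 1). PGR and CCND1 (−1.01 ± 0.23, adjusted p = 0.00646) were lower and the chemokine CXCL12 was higher. This list was barely past the threshold (camera adjusted p = 0.0411, and adjusted p = 0.373 with an estimated correlation), and 9 of the 19 fits without 1 sample lost it, with medians from −1.12 to −0.70 over all 19. It was also lost in the CW or EM style (median −0.59, adjusted p = 0.191), with style as a block, with the stricter filter and with the mean of probes (adjusted p = 0.0627, 0.0887 and 0.0599).

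Steroid receptors changed in opposite directions. ESR1, the estrogen receptor alpha gene, averaged 8.72 ± 1.31 (SD, n = 10) in endometriomas and 11.78 ± 0.73 (SD, n = 9) in controls, 8.39-fold lower (limma adjusted p = 0.000324). ESR2, the beta receptor gene, was 1.95-fold higher (0.96 ± 0.20, adjusted p = 0.00280), although it was detected in only 2 of 9 controls, and the progesterone receptor PGR was 4.79-fold lower (−2.26 ± 0.46, adjusted p = 0.00279). RORB, an orphan receptor, fell 10.7-fold. Over the receptor list 6 of 17 genes rose and 3 fell, the same as when adjusted over the list alone, and its median of 0.30 lay within chance (camera adjusted p = 0.113), with a mean of −0.02.

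Some genes of steroid-producing and gonadal cells were higher. NR5A1, the master regulator of steroidogenic genes, averaged 6.91 ± 1.06 (SD, n = 10) against 5.21 ± 0.30 (SD, n = 9), 3.26-fold higher (limma adjusted p = 0.00274). HSD11B1, which regenerates cortisol, was higher by 4.00 on the log2 scale (SE 0.45, adjusted p = 5.67e-05) and the lipoprotein receptor SCARB1 2.83-fold higher. STAR, the cholesterol transporter of steroid synthesis, and the gonadal factor GATA4 were each detected in 8 of 10 endometriomas and 0 of 9 controls. Without the detection filter they were at least 5.39-fold and at least 3.01-fold higher (limma adjusted p = 0.0107 and 0.00355). CYP19A1, the aromatase gene, was detected in 5 of 10 endometriomas and 0 of 9 controls and was not past the threshold there (adjusted p = 0.166), and neither was HSD17B1 in the main comparison (0.65 ± 0.37, adjusted p = 0.236). In the steroid synthesis list 3 of 14 members rose and 2, HSD11B2 (−2.17) and NR5A2 (−0.80), fell (adjusted over the list alone, 4 and 2). Those falls were lost in 2 and 1 of the 19 fits without 1 sample. The list had a median of 0.50 (camera adjusted p = 0.0144, and adjusted p = 0.323 with an estimated correlation).

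The gonadal list had 5 of 9 members higher and none lower, the same as when adjusted over the list alone. AMHR2, the receptor of anti-Müllerian hormone, was 13.6-fold higher (3.76 ± 0.66, adjusted p = 0.000867) and GATA6 2.29-fold higher (1.20 ± 0.23, adjusted p = 0.00210). The list median was 1.20 (camera adjusted p = 0.000793, and adjusted p = 0.323 with an estimated correlation) and stayed at that value with DLK1 at its bound. The median was 1.54 in the CW or EM style and 0.59 in the other, where the list was not called (adjusted p = 0.276). A detection filter that required every sample of a group ended the call as well (median 0.56, adjusted p = 0.117). The rise was not seen in every lesion. In 2 endometriomas of the other style the list score was 6.09 and 6.14, within the controls' range of 5.92 to 6.97.

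**Figure D2:**
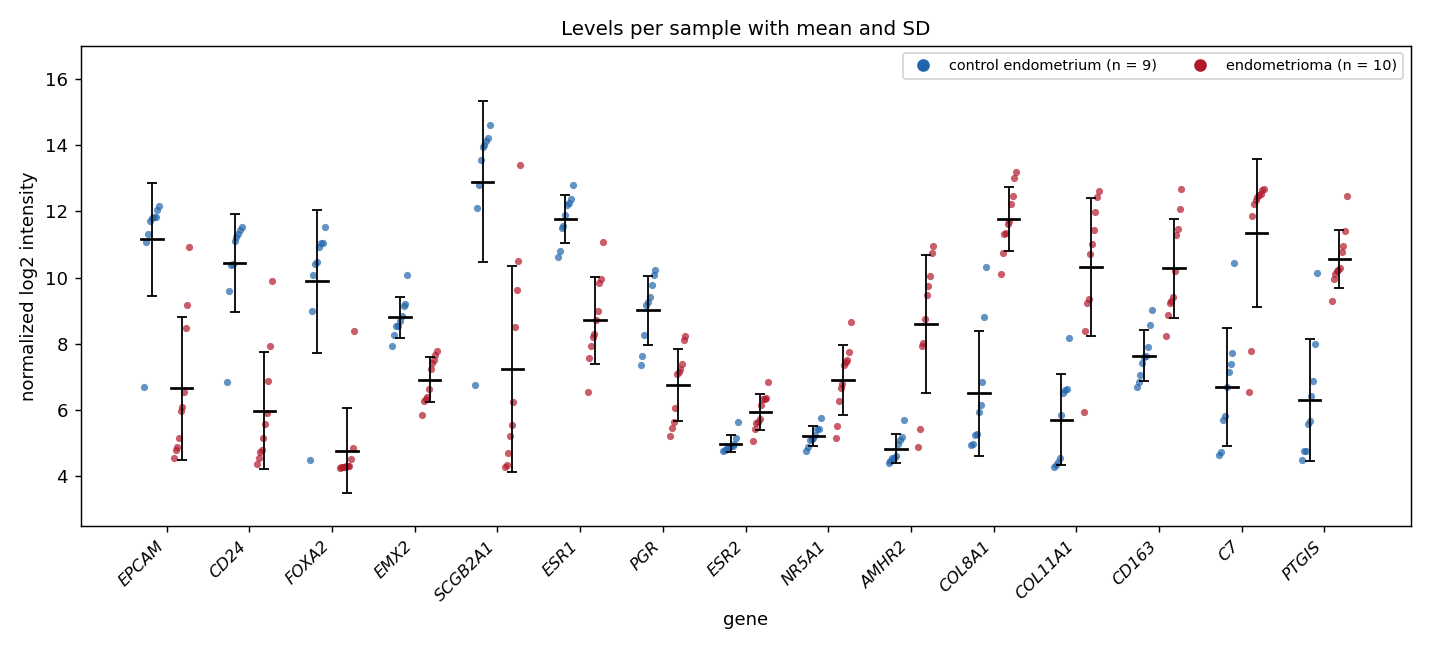
Normalized log2 intensity (vertical axis) of 15 genes in each control endometrium sample (blue, n = 9) and each endometrioma (red, n = 10); the thick line is the group mean and bars are 1 SD. ESR1 averages 11.78 in controls and 8.72 in endometriomas, while NR5A1 averages 5.21 and 6.91, with overlapping samples for most genes shown.

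Matrix genes rose in part. In the fibrillar and fibrosis matrix list 16 of 33 members rose and none fell (adjusted over the list alone, 22 rose and 1 fell). COL8A1 averaged 11.77 ± 0.97 (SD, n = 10) against 6.51 ± 1.88 (SD, n = 9). COL14A1 rose 2.78-fold (limma adjusted p = 0.00111). The list median was 1.12 (camera adjusted p = 1.85e-10, and adjusted p = 0.323 with an estimated correlation), with 0.87 and 0.55 in the CW or EM and other styles. Basement membrane genes split, with 5 of 19 higher and 2 lower, the same as when adjusted over the list alone. Nidogen NID2 was 3.67-fold higher (1.88 ± 0.28, adjusted p = 0.000245) without overlap between the groups and the laminin LAMA4 2.39-fold higher, while the epithelial laminin chain LAMA5 was 2.03-fold lower (−1.02 ± 0.23, adjusted p = 0.00557). Camera gave this list an adjusted p of 0.412, in the upward direction against a median of −0.15, and in the other style it was called upward (median 0.38, adjusted p = 0.0279).

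Few contractile genes passed on their own. Of 21 members 4 rose and none fell (adjusted over the list alone, 8 rose). TAGLN was 2.02-fold higher (1.02 ± 0.26, adjusted p = 0.0120), PLN 3.64-fold and smooth muscle actin ACTA2 1.62-fold. In the other description style these differed by −0.06, −0.44 and −0.13 on the log2 scale. The list median was 0.75 (camera adjusted p = 0.000390, and adjusted p = 0.373 with an estimated correlation). Without 1 control it was 1.17. It was 1.33 in samples with CW or EM codes and −0.77 in the other 7, each past camera's threshold in its own direction at the preset correlation. The estimated correlation of this list was 0.636, and neither style was tested with it. The other style held only 2 controls, with list scores of 11.64 and 9.31. The difference between styles in the list score had an adjusted p of 0.0451 over the 36 lists (limma interaction on scores, chosen after seeing the data). The score difference between styles was 2.49 ± 0.65 (unadjusted p = 0.00125). Without 1 control that resembled the endometriomas it was 1.32 ± 0.64 (unadjusted p = 0.0548, adjusted p = 0.818). That fit has 1 control left in the other style, assumed to vary like the other groups.

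Among regulators of epithelial-mesenchymal transition 4 of 20 members rose and 1 fell (adjusted over the list alone, 5 and 1). ZEB2 was 1.69-fold higher (0.76 ± 0.16, adjusted p = 0.00360), ZEB1 differed by −0.27 ± 0.21 (adjusted p = 0.381) and TWIST2 was 3.86-fold lower (−1.95 ± 0.40, adjusted p = 0.00286). Its median was 0.42 (camera adjusted p = 0.0228, and adjusted p = 0.323 with an estimated correlation), and 0.19 in the other style, where it was not called (adjusted p = 0.366). Metalloproteinases and their inhibitors went both ways, with 5 of 25 higher and 4 lower, the same as when adjusted over the list alone. MMP23B was 2.60-fold higher (1.38 ± 0.21, adjusted p = 0.000273), MMP9 5.11-fold, and the inhibitors TIMP2 and TIMP1 2.05-fold and 2.01-fold. MMP7, an epithelial metalloproteinase, differed by −3.45 ± 1.06 (adjusted p = 0.0317, lost in 8 of the 19 fits without 1 sample), while MMP11 (−1.28 ± 0.89) and TIMP3 (−0.10 ± 0.34) did not pass. The list was called at a camera adjusted p of 0.0361 (adjusted p = 0.373 with an estimated correlation), with a median of 0.42 and a mean of 0.08, and 5 of the 19 fits without 1 sample lost the call. It was also lost in each style alone (adjusted p = 0.0731 and 0.151), with 75th percentile centring (0.0568), with the stricter filter (0.208) and without both samples nearer to the other group (0.0801).

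Macrophage transcripts rose as a group. In the macrophage and monocyte list 20 of 24 members rose and none fell (adjusted over the list alone, 22 rose). The scavenger receptor CD163 averaged 10.28 ± 1.51 (SD, n = 10) against 7.64 ± 0.77 (SD, n = 9), 6.22-fold higher (limma adjusted p = 0.00227). Lysozyme LYZ was 4.63-fold, the folate receptor FOLR2 3.64-fold and stabilin STAB1 3.20-fold higher. Their median was 1.78 (camera adjusted p = 1.19e-12, and adjusted p = 0.323 with an estimated correlation), with 1.91 and 0.97 in the CW or EM and other styles. Complement genes moved with them, and 3 tested genes stand in both lists. Of 21 complement genes 9 rose and none fell (adjusted over the list alone, 11 rose). C7, of the terminal complement pathway, was 25.2-fold higher (4.66 ± 0.87, adjusted p = 0.00151), C1QA 3.73-fold and C1S 2.51-fold. C3 differed by 2.49 ± 0.73 (adjusted p = 0.0252), a call lost in 2 of the 19 fits without 1 sample. The complement median was 1.15 (camera adjusted p = 3.85e-05, and adjusted p = 0.323 with an estimated correlation).

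Other immune lists were less uniform. MHC class II genes had 5 of 12 members higher and none lower (adjusted over the list alone, 6), with a median of 1.37 (camera adjusted p = 0.00105, and adjusted p = 0.373 with an estimated correlation). Single members were near the threshold, such as HLA-DPA1 (1.43 ± 0.47, adjusted p = 0.0430), a call lost in 12 of the 19 fits without 1 sample. Neutrophil markers had 5 of 14 higher and none lower (adjusted over the list alone, 7), including MNDA (3.92-fold) and FPR1 (3.85-fold), with a median of 1.19 (camera adjusted p = 0.000131, and adjusted p = 0.373 with an estimated correlation). For T cell markers the median was 0.77 (camera adjusted p = 0.000574, and adjusted p = 0.373 with an estimated correlation), though only CD6 of 19 genes passed, a call lost in 4 of the 19 fits without 1 sample, and none passed when adjusted over the list alone. B and plasma cell markers had 4 of 9 higher and none lower (adjusted over the list alone, 5), including CD22 (2.10-fold, adjusted p = 0.00985) and the joining chain JCHAIN (9.34-fold, adjusted p = 0.0212). Their median was 0.51 (camera adjusted p = 0.0144, and adjusted p = 0.373 with an estimated correlation). The call was lost in the CW or EM style (adjusted p = 0.0817), with the stricter filter (median 0.0291, adjusted p = 0.502) and without both samples nearer to the other group (adjusted p = 0.0657).

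Natural killer cell markers had a median of −0.55, with 2 of 14 lower (adjusted over the list alone, 3), and were not called (camera adjusted p = 0.108). Leaving out 1 sample at a time moved the median between −0.71 and −0.29 (adjusted p up to 0.312). They were called with 75th percentile centring (adjusted p = 0.0431), without control replicate 2 (0.0473) and without endometrioma replicate 9 (0.0478). Granulysin GNLY, a cytotoxic granule protein abundant in uterine natural killer cells, was 13.7-fold lower (−3.77 ± 0.81, adjusted p = 0.00376). Mast cell markers were not called (median 0.80, camera adjusted p = 0.364), and only GATA2, which is also a progesterone-related factor of endometrium, fell among 8 (−2.02 ± 0.34, adjusted p = 0.000635). Chemokines and cytokines had 4 of 29 higher and none lower, the same as when adjusted over the list alone. CXCL12 was 3.20-fold higher (adjusted p = 0.00539; −0.15 on the log2 scale in the other description style) and CCL2 4.12-fold (adjusted p = 0.0128). Their median was 0.71 (camera adjusted p = 0.00988, and adjusted p = 0.373 with an estimated correlation), and the call was lost in the CW or EM style (adjusted p = 0.0817). Interferon-stimulated genes had 11 of 27 higher and none lower (adjusted over the list alone, 14). BST2 was 3.92-fold higher (1.97 ± 0.43, adjusted p = 0.00466) and MX1 2.44-fold (adjusted p = 0.00557). Their median was 0.50 (camera adjusted p = 6.55e-06, and adjusted p = 0.323 with an estimated correlation).

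**Figure D3:**
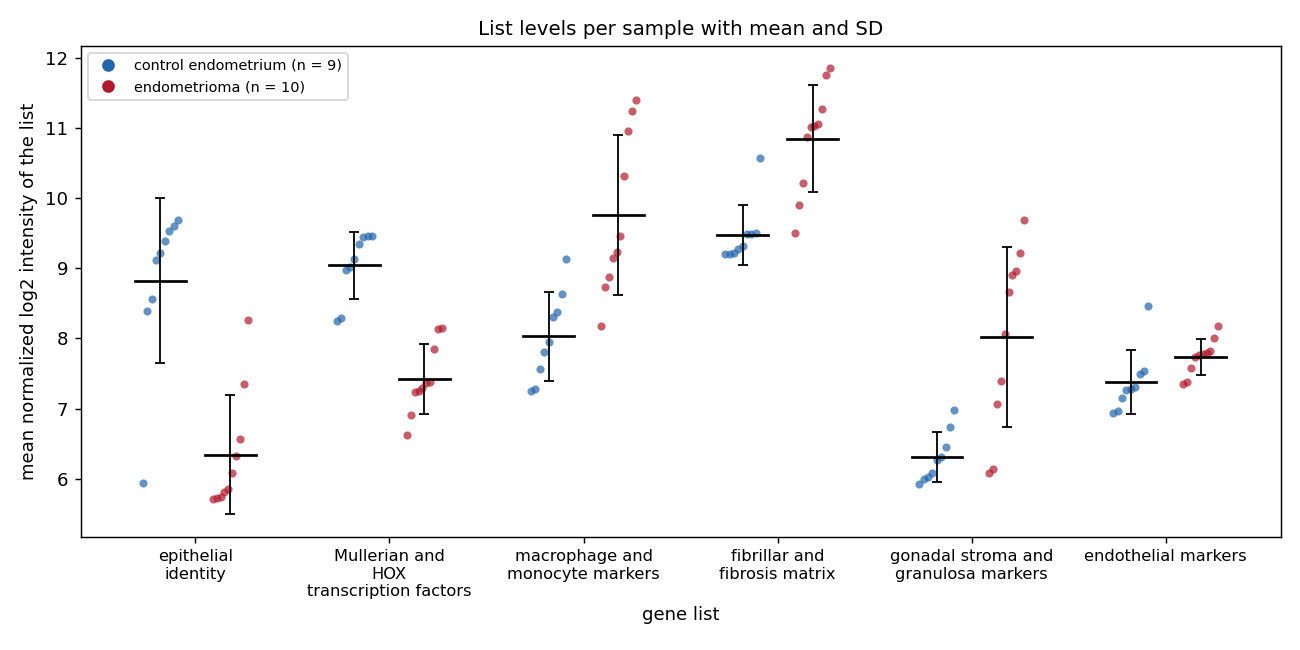
Mean normalized log2 intensity of the tested members of 6 gene lists (vertical axis) in each control endometrium sample (blue, n = 9) and each endometrioma (red, n = 10); the thick line is the group mean and bars are 1 SD. The epithelial list averages 8.83 in controls and 6.34 in endometriomas, and the macrophage list 8.03 and 9.76; 1 control lies among the endometriomas for the epithelial list.

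Markers of other tissue components varied. LYVE1, a lymphatic vessel and macrophage receptor, was 6.94-fold higher (2.80 ± 0.52, adjusted p = 0.00150) and the endothelial claudin CLDN5 2.29-fold. Over 26 endothelial genes 3 rose and 1 fell, the same as when adjusted over the list alone, with a median of 0.32 (camera adjusted p = 0.00591, and adjusted p = 0.373 with an estimated correlation). The median in the other description style was 0.09 (adjusted p = 0.127), and leaving out 1 control at a time moved it between 0.21 and 0.50. The fatty acid carrier FABP4 was 7.66-fold higher without overlap (2.94 ± 0.34, adjusted p = 5.69e-05) and lipoprotein lipase LPL 2.88-fold. These were the 2 of 8 adipocyte genes that rose, also over the list alone, and none fell (median 0.50, camera adjusted p = 0.0177, and adjusted p = 0.323 with an estimated correlation). Of 7 neural and Schwann cell genes UCHL1 (6.09-fold), NTRK2 (4.15-fold) and NEFH (3.18-fold) were higher and none was lower (adjusted over the list alone, 3 and 2). That list had a median of 1.08 (camera adjusted p = 0.0309, and adjusted p = 0.323 with an estimated correlation). Without control replicate 6 the call was lost (adjusted p = 0.0603), and the median was −0.40 in the other style (adjusted p = 0.932) and −0.0151 without the detection filter (adjusted p = 0.174). With the mean of probes the adjusted p was 0.0510. Mesothelial genes went both ways, with 3 of 14 higher and 3 lower (adjusted over the list alone, 3 and 4; camera adjusted p = 0.567). Podoplanin PDPN was 2.74-fold and P-cadherin CDH3 6.79-fold higher, while KLK11 was 6.89-fold lower.

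Heme oxygenase HMOX1, which degrades heme, averaged 10.32 ± 1.31 (SD, n = 10) against 7.01 ± 0.37 (SD, n = 9), 9.95-fold higher without overlap (limma adjusted p = 8.60e-05). Ferritin light chain FTL was 1.78-fold higher (0.83 ± 0.12, adjusted p = 0.000242) and ceruloplasmin CP 10.4-fold lower (−3.38 ± 0.79, adjusted p = 0.00677). Of 21 iron and heme genes 6 rose and 1 fell (adjusted over the list alone, 6 and 2). The median was 0.37 (camera adjusted p = 0.0258, and adjusted p = 0.373 with an estimated correlation), and the call was lost without endometrioma replicate 1 (median 0.26) and without 1 control (median 0.32). Without endometrioma replicate 9 the median was 0.22 (adjusted p = 0.0336). The call was also lost in the CW or EM style (adjusted p = 0.0817), with array weights (0.0733) and without both samples nearer to the other group (0.0801). No erythroid gene of 5 passed, also over the list alone. HBB differed by 1.04 ± 0.56 (adjusted p = 0.204) and the list median was 1.27 (camera adjusted p = 0.0361, and adjusted p = 0.373 with an estimated correlation), a call lost in 5 of the 19 fits without 1 sample, with medians from 0.78 to 1.56, in each style alone (adjusted p = 0.0517 and 0.129) and with array weights (0.0756).

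In the prostaglandin pathway 4 of 23 genes rose and 1 fell (adjusted over the list alone, 6 and 1). PTGIS averaged 10.57 ± 0.88 (SD, n = 10) against 6.30 ± 1.84 (SD, n = 9). The phospholipases PLA2G2A and PLA2G5 were 6.97-fold and 3.88-fold higher and the receptor PTGER4 3.77-fold, while the cyclooxygenase PTGS2 differed by 0.52 ± 0.99 (limma adjusted p = 0.747). The list median was 0.52 (camera adjusted p = 0.0144, and adjusted p = 0.373 with an estimated correlation) and 0.06 in the other style (adjusted p = 0.524). Wnt genes exchanged members, with 7 of 27 higher and 5 lower (adjusted over the list alone, 8 and 7; camera adjusted p = 0.731). The receptor FZD7 was 9.48-fold higher (3.24 ± 0.38, adjusted p = 5.69e-05) and FZD4 2.33-fold, whereas FZD10 was 4.28-fold, FZD6 2.06-fold and the inhibitor DKK1 11.5-fold lower. SFRP1 (−0.31 ± 0.64) and the growth factor IGF1 (−0.36 ± 0.59) did not pass.

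In growth and metabolic lists few genes passed. No gene of the 32 in the cell cycle list passed, over all genes or over the list alone. TPX2 differed by −1.14 ± 0.58 (adjusted p = 0.182), and by 0.57 in the other description style. Their median was −0.79 (camera adjusted p = 0.00988, and adjusted p = 0.628 with an estimated correlation). The call was lost without control replicate 5 (median −0.52, adjusted p = 0.0684), and the median was 0.41 in the other style (adjusted p = 0.0108). In the oxidative phosphorylation list 5 of 32 genes fell and none rose, the same as when adjusted over the list alone, by small amounts such as −0.40 ± 0.10 for ATP5F1B (adjusted p = 0.0112) and −0.41 ± 0.11 for COX6C (adjusted p = 0.0158). The median of −0.27 (camera adjusted p = 0.00230, and adjusted p = 0.373 with an estimated correlation) became −0.03 with centring on the 75th percentile (adjusted p = 0.383). Hypoxia and glycolysis genes were not called (1 of 26 higher, 2 lower, none over the list alone; camera adjusted p = 0.722), although in the other style they were called upward (median 0.32, adjusted p = 0.000441). Not called either were genes of DNA methylation and microRNA processing (2 of 13 lower, none higher, also over the list alone; camera adjusted p = 0.108), where DNMT1 was 1.51-fold lower (−0.60 ± 0.17, adjusted p = 0.0200). Among 27 immediate-early genes 2 rose and 1 fell (adjusted over the list alone, 1 and 0), with KLF2 3.23-fold higher (adjusted p = 0.00382). That list's median was 0.40 (camera adjusted p = 0.0320, and adjusted p = 0.622 with an estimated correlation), and 6 of the 19 fits without 1 sample lost the call (medians 0.31 to 0.60), as did the stricter filter (adjusted p = 0.0753).

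Across the 36 lists camera called 21 higher and 7 lower at the preset correlation. None was called with estimated correlations, whose median was 0.266. By fry 14 lists moved higher and 7 lower. Among the lists called by camera, fry did not pass for smooth muscle (adjusted p = 0.0890), T cell (0.0938), endothelial (0.0671), MHC class II (0.0575), erythroid (0.0889), chemokine (0.103), immediate-early (0.337) and cell cycle genes (0.266). It passed for the DNA methylation and microRNA list (0.0381), which camera did not call.

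Samples varied to a similar extent within each group. The root mean square deviation from the group mean was 0.594 ± 0.089 (SD, n = 10) in endometriomas and 0.581 ± 0.139 (SD, n = 9) in controls on the log2 scale (exact permutation test, two-sided, p = 0.822). Median correlations between samples were 0.906 within endometriomas, 0.905 within controls and 0.854 between groups. By mean correlation 1 control and 1 endometrioma lay nearer to the other group. Without both, 1476 genes were higher and 1578 lower, an alternative chosen after seeing the data that favours larger counts by its selection. Of the main calls 1032 and 1083 were shared with it.

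With only 2 controls in the other style, a dependence of the group difference on description style was hard to detect. The limma interaction term gave 0 genes at an adjusted p under 0.05 and 1248 at an unadjusted p under 0.05, 9.96% of those tested where chance gives 5%. With the group accounted for, 0 genes passed for a difference between styles at an adjusted p under 0.05 (limma). At an unadjusted p under 0.05 there were 871 of 12530, more than the 5% that chance gives. A style difference is therefore not excluded. Within the CW or EM style 1187 genes were higher and 1103 lower, and 849 and 845 of the main calls were among them. Within the other style, with 5 endometriomas and 2 controls, 0 genes passed in either direction. With style as a block 765 genes were higher and 751 lower.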

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

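The comparison of list scores between description styles, and the tests of 1 control that resembled the endometriomas, were chosen after the results were seen. Outlying samples were looked for in 160 groups of values by a fixed ratio, the gap between an extreme sample and its neighbour divided by the range of the group. This found 31, where chance gives about 8 at 1 in 20. Of these, 21 were in controls, and 16 of the 21 came from 1 control, which correlated more with the endometriomas than with its own group.

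Among epithelial genes 1 control lay far below the others. The ratio was 0.652 for the epithelial list, 0.804 for EPCAM, 0.673 for CLDN3, 0.666 for PRSS8, 0.641 for FOXA2, 0.587 for CD24, 0.541 for UGT2B7, 0.536 for C9orf152 and 0.682 for the secretoglobin SCGB2A1. In endometriomas 1 sample lay far above the rest for FOXA2 (0.852), C9orf152 (0.883), CLDN3 (0.514), the ciliated list (0.638) and the glycodelin gene PAEP (0.515). These ratios do not say whether it was the same sample each time.

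Matrix and muscle values set single controls apart in the other direction. A control lay far above the rest for the fibrillar matrix list (0.782), the smooth muscle list (0.620), the endothelial list (0.603), the iron list (0.729) and the metalloproteinase list (0.511). The same held for COL10A1 (0.877), CLDN11 (0.868), DLK1 (0.826), DIRAS3 (0.811), PDLIM3 (0.621) and ESR2 (0.553). For DLK1 no control was detected, so that ratio describes values at background. An endometrioma lay lowest for the smooth muscle list (0.502), the immediate-early list (0.477) and HOXC6 (0.471), and highest for the hypoxia list (0.5). For oxidative phosphorylation the lowest sample stood apart in controls (0.571) and in endometriomas (0.481).

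The smooth muscle list differed between description styles, with an adjusted p of 0.0451 for the difference of effects. The score difference was 1.46 in the CW or EM style and −1.03 in the other. The difference between these was 2.49 ± 0.65 (limma SE, unadjusted p = 0.00125). Without the control that resembled the endometriomas it was 1.32 ± 0.64 (unadjusted p = 0.0548), with 1 control left in the other style and the spread taken from all groups. This does not decide whether the style difference rests on that control.

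That control correlated more with the endometriomas under all 3 other processings as well. A wrong label stays open, because 0 of 10 endometriomas reached its Müllerian and HOX score but the margin was under 1 SD of the endometriomas. A low share of epithelial cells may account for part of the likeness, and 5 of 10 endometriomas had an epithelial score at least as high. That count cannot decide it. The sample was picked for its likeness to the endometriomas, in which the epithelial list is lower. In smooth muscle score 0 of 8 other controls and 0 of 10 endometriomas were as high, a count that only restates that this sample was the highest. Its score was 11.64, against 9.31 for the next control and 10.49 for the highest endometrioma, so it lay well above both groups. Whether more smooth muscle in the piece of tissue adds to the likeness stays open, because no test separated this from the other explanations. The tests covered the label and the makeup of the sample. The design names no group that gives a biological explanation, and none was tested.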

How the results depend on the processing

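The analyses of the other description style alone, without both samples nearer to the other group, and of the other style without 1 control, were chosen after the data were seen. Counts of genes and lists stayed within 1.5 times the main values under centring on the 75th percentile, the authors' value table, both other detection filters, the mean of a gene's probes, style as a block, the CW or EM style alone and trend and robust variance. With all probes and with the exact rank-sum test this held for the counts of genes, and lists were not tested. With each sample left out, genes higher ranged from 740 to 1449 and lower from 749 to 1632, those at least 2-fold from 471 to 785 and from 414 to 677, and lists from 18 to 21 and from 5 to 8. Without background correction 396 genes were at least 2-fold higher and 341 lower, where unremoved background compresses folds. At an adjusted p under 0.01 there were 442 higher and 385 lower genes, 341 and 288 of them at least 2-fold, as a stricter threshold must give fewer. Array weights gave 2388 and 2776, with 1039 and 876 at least 2-fold; the cause was not tested. In the other style 0 genes passed in each of the 4 counts, with 2 controls left. Camera with estimated correlations called 0 lists in each direction. The style interaction called 4 genes without background correction and 2 without the detection filter, against 0; the cause was not tested. No fit with the BeadChip as a block was run, because no file used here names the chips. Dim genes are limited by signal over background.

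The spread difference (0.0127, not past its test) became −0.00139 as a correlation with the rest of the group, and ranged from −0.00707 to 0.0667 with each sample left out. List medians changed sign for hypoxia with 75th percentile centring (0.0605), neural genes without the detection filter (−0.0151), mesothelial genes with style as a block (−0.0267), Wnt genes in the CW or EM style (0.10), and basement membrane genes with the stricter filter (0.0310), in the CW or EM style (0.0254), without both samples (0.12) and with samples left out (−0.189 to 0.0679). In the other style the medians were 0.41 for cell cycle, −0.13 for receptors, 0.38 for basement membrane, −0.77 for smooth muscle, −0.63 for mast cell, −0.30 for mesothelial, 0.32 for hypoxia and −0.40 for neural genes. Genes that changed sign there were MEIS2 (−0.67), CXCL12 (−0.15), MCM4 (0.00969), TPX2 (0.57), TAGLN (−0.0616), ACTA2 (−0.13), PLN (−0.44), CALD1 (−0.0232), CTSG (−0.34), CPA3 (−0.80), ACACB (−0.58), MMP15 (0.0552) and SLC2A1 (0.19). Within the other style the smooth muscle score difference of −1.03 became 0.136 without the control nearer to the endometriomas, with 1 control left. TIMP3 changed to 0.24 with array weights and 0.0120 without both samples. With each sample left out TIMP3 ranged from −0.207 to 0.112 and SFRP1 from −0.597 to 0.00397. The causes of these changes were not tested. Of 172 named genes 141 passed, 110 of them with every sample left out in turn. Other settings also cost calls of named genes. The exact rank-sum test lost 32, style as a block 25 and the fit without the detection filter 13. In the CW or EM style 23 were lost and 2 gained. Array weights went mostly the other way, with 17 gained and 1 lost.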

Other observations

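The tests of the macrophage pattern, and the genes named in the next paragraph, were chosen after the results were seen. The predictions for NR5A1 and STAR and the counts over other splits were written before their results.

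Besides DLK1, 8 genes past the threshold were detected in no control. Those with the highest bounds were LOC100240735 (at least 3.08-fold higher) and VSNL1, a neuronal calcium sensor (at least 2.12-fold).

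Relative to 6 of 13 other lists of cell types, the macrophage score shifted upward at an adjusted p under 0.05 (exact permutation test). Of these 6, the natural killer (−0.716), mesothelial (−0.0912) and ciliated (−1.28) scores were themselves lower in endometriomas. For them the gap does not compare 2 rises. The score of the macrophage list, taken minus the endothelial score, was 1.37 higher in endometriomas (exact permutation test, two-sided, p = 0.00303, adjusted p = 0.00985 over 13 lists). A lower share of epithelial cells alone would raise both by a similar amount, apart from dim genes, whose differences the offset understates. With endothelial genes, 1 of the 13 possible references, this difference argues against that share as the whole cause. The macrophage list shifted by at least 0.965 in each description style taken alone, which argues against style, as labelled, as the whole cause. The other style held only 2 controls, and most of its endometriomas had M codes that no control had. A collection round within that style therefore stays open. With the macrophage score taken minus theirs, the natural killer (2.44), T cell (0.964), mast cell (1.29), mesothelial (1.82) and ciliated (3) lists also passed. Adjusted p-values did not pass for B and plasma cell (0.0621), adipocyte (0.0621), smooth muscle (0.132), neural (0.155), neutrophil (0.290), erythroid (0.454) and gonadal lists (0.986). More macrophages in the cyst wall remain a candidate explanation, and higher transcription per macrophage was not tested.

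Of 3 steroidogenic genes tested, NR5A1 and STAR varied with the gonadal markers between endometriomas and HSD11B1 did not pass. Over the 10 endometriomas NR5A1 correlated with the score of 8 other gonadal markers, with Pearson r = 0.925 (permutation p = 0.00014, adjusted 0.00042 over 3 genes) and a Spearman correlation of 0.939 (permutation p = 0.00028). STAR gave r = 0.899 (permutation p = 0.00091, adjusted 0.00136) and a Spearman correlation of 0.770 (permutation p = 0.0121). Without the 2 endometriomas farthest from the median, r was 0.815 and 0.748. HSD11B1 gave r = 0.0636 (permutation p = 0.861) and a Spearman correlation of −0.0667 (permutation p = 0.866), and r = −0.609 without those 2. Ovarian tissue in the samples may thus account for part of the rise in NR5A1 and STAR, but expression of the same genes by the lesion itself would give the same correlation and stays open.

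Of 100 splits of the 19 samples into 10 and 9, the real one included, only the real split gave as many genes as 1050 higher and 1107 lower, or as 608 and 520 at least 2-fold. The highest other values were 925, 915, 520 and 469, and chance as the source of these counts can be excluded at this number of splits. Apart from the real split, the one with the most calls, 1840 genes, was close to the mirror of the real one, with 8 endometriomas in its smaller group. For the 21 lists that were higher the highest other value was 17, while the other splits gave a median of 5 lists higher and 5 lower. For the 7 lower lists, 32 of the 100 splits gave as many and the highest other value was 17, so chance cannot be excluded for that count.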
